A study of Mus musculus with 4 samples.

How the data were processed

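RNA was sequenced from primary keratinocytes of newborn C57BL/6 mice, with 2 mock libraries and 2 libraries stimulated with IL-25 for 8 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a commercial tissue kit and the libraries were made by a sequencing institute. Per the submitters' processing notes, HISAT2 and featureCounts were used and the genome build was mm10, with no versions given. The annotation, the strandedness and the read length are not given in the sources used here. The authors deposited 1 table of RPKM values per library (reads scaled by exon length and by the library's total), with gene symbols. Each RPKM divides a gene's reads by its length and by the library's total, so a few abundant genes can lower the values of the rest. No duplicate removal or bias correction is recorded in the sources used here.

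The design fixed before the data were examined assumed read counts. Since the deposited values were RPKM, the main fit was limma on log2 values instead of a count model. edgeR and DESeq2 were not run. Of 17297 genes, 27 had a value of 0 in all libraries, and the date-like symbol 2-Mar stood on 2 lines, which were kept apart. Whole reads were recovered from the RPKM steps with the gene lengths of GENCODE M21 (mm10), whose symbols matched 16807 genes. Reads of 14892 genes came from the reference exon length, and those of 2378 genes from the smallest set of whole numbers that fits, where a common factor can remain. All of the 68546 values above 0 (100.0%) were whole within 0.02 read. The method accepts or fits a length by this same criterion, so that share does not check the recovered reads. On simulated data, 99.6% of genes and 4 of 4 library totals were recovered exactly (95.8% of the genes without a reference length). The library totals were 18447629, 18409897, 17673618 and 17636368 reads, and intervals for low reads would cover counting error only. Recovered reads were used for filtering, scaling factors and limma-voom, and coordinates are 1-based gene bounds from GENCODE M21.

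Genes with at least 10 reads in at least 2 libraries were tested (15229). RPKM values were divided by TMM factors (0.886, 0.884, 1.13 and 1.13; trims of 30% of ratios and 5% of abundances), 0.1 RPKM was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3 with an abundance trend, on all 4 libraries with group as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p of a gene comes from this limma test. Log2 changes are on the log2(RPKM + 0.1) scale, which understates changes of low genes, and errors of log2 changes are SE. Means ± SD are of deposited RPKM before TMM scaling. For genes well above 0.1 RPKM in both groups, their log2 ratio therefore lies above the reported change by the log2 ratio of the groups' TMM factors. This gap is slightly above the 0.34 by which the median gene moved with library size only. For lower genes the added 0.1 RPKM makes the gap differ. Gene list tests used limma's camera on the same values with a preset correlation of 0.01, with adjustment over 33 lists of at least 3 tested genes, and again with an estimated correlation. Lists added after the data were seen were adjusted among themselves. fry was run as an alternative. On data simulated for the comparison of IL-25 with mock (14331 genes tested), the fit called 23.4% of genes changed 1.25-fold, 44.7% at 1.5-fold, 60.9% at 2-fold and 89.8% at 4-fold, and 1 unchanged gene. Only 46 to 49 tested genes were changed at each fold there, against 11737 genes called in the data. The adjusted threshold was therefore stricter in the simulation, and these rates do not describe detection in the data. Of 200 random lists of 20 unchanged genes (14328 genes tested), 4.5% had a camera p below 0.05 and 0 passed adjustment. These genes were simulated independently, so this rate does not describe lists of correlated genes in the data. For a list of independently simulated genes raised 1.5-fold, the camera p was 4.89e-59 with the preset and 0.00298 with an estimated correlation. The second form thus gave a far larger p, but this 1 list of independent genes does not measure its power in the data. Reconstruction and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

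The 33 lists were fixed before the data were examined: IL-25 receptor and signalling, chemokines, cytokines, NF-kB, STAT3, antimicrobial peptides, wound keratins, S phase, G2 and M phase, basal and differentiating epidermis, interferon-stimulated genes, antigen presentation, immediate early genes, EGFR ligands and growth factors, matrix proteases, glycolysis and hypoxia, cholesterol and fatty acid synthesis, unfolded protein and integrated stress response, heat shock, oxidative stress, p53 targets, Notch, collagen and TGF-beta, hair follicle, markers of fibroblasts, melanocytes, leukocytes, mast cells, endothelium, muscle, and adipocytes, Schwann cells and red cells, and RNA quality. Genes were named by a rule fixed at the same time. It took, among called genes with non-overlapping groups and a mean of at least 1 CPM from the recovered reads, the 12 largest changes and the 5 smallest p in each direction. It also took up to 4 members per list with the smallest p, all called members of lists with at most 10, 15 genes named in advance, and the 10 most abundant genes. Some genes that the rule took are not reported here. Genes named in the closing section from added lists were chosen after their values were seen. Alternatives were RLE factors, library size only, other read filters, limma-voom on recovered reads, a test against a 1.5-fold change, a replicate block, each library left out in turn, and, chosen after seeing the data, pseudocounts of 1 and 0.01 RPKM and a spline correction for GC content and length. With a library left out, the lone library was assumed to vary like the other group. GC content was known for 97.2% of genes.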

Results

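Gene expression was measured by RNA sequencing in primary keratinocytes, the main epithelial cells of the epidermis, grown in M154CF medium from the skin of newborn C57BL/6 mice. The cells were left unstimulated (mock) or were stimulated for 8 h with IL-25, a cytokine of the IL-17 family also called IL-17E. Each group had 2 libraries. The library totals behind the deposited RPKM values, as recovered from their steps, were 18447629 and 18409897 reads in the mock libraries and 17673618 and 17636368 in the IL-25 libraries, and the reads on the genes analysed here came to 18398475, 18360415, 17619909 and 17581988. A single read on 1 kb of exon was worth 0.0542 to 0.0567 RPKM. Between 17126 and 17149 genes had at least 1 read in each library. The most abundant transcripts were those of the basal keratins Krt5 and Krt14, which together with 8 other genes (Krt17, Krt1, Actb, Dsp, Hsp90ab1, Eef2, Eef1a1 and Jun) had the highest mean read counts. The 10 most abundant genes of each library held 4.89% and 4.98% of reads in mock and 6.33% and 6.37% in IL-25. Nothing in the labels says that the 2 libraries of a group came from separate cultures or animals. The p-values of genes therefore measure only the spread between these libraries, which may be technical. Camera p-values compare a list's genes with other genes and do not measure a spread between cultures.

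The comparison asked how 8 h with IL-25 changed the expression of all genes in cultured keratinocytes. Keratins of wounded epidermis (Krt6a, Krt16 and Krt17) and matrix proteases and their inhibitors (Mmp9 and Serpinb2) were lower in the IL-25 libraries, as were Il24 and Inhba. Keratins of the first suprabasal layer, Krt1 and Krt10, were higher, as were most listed genes of the hair follicle, mitotic genes and several immediate early genes. Genes of the integrated stress response and of the antioxidant response were lower. The list calls behind these statements were lost with an estimated correlation between genes (adjusted p = 0.502 with an estimated correlation for each). That form also gave a far larger p than the preset for a simulated list of independent genes. Its power in these data was not measured, so the loss neither shows nor excludes correlated genes. The estimated correlations ran from -0.105 for wound keratins to 0.116 for antioxidant genes, on both sides of the preset 0.01. Il17rb, the IL-25 receptor subunit, was present at a low level in both groups and was higher with IL-25.

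Of 15229 genes tested with limma, 11737 (77.1%) passed a Benjamini-Hochberg adjusted p of 0.05, with 6057 higher and 5680 lower in IL-25. Among these, 4342 differed at least 2-fold, 2392 of them higher and 1950 lower. Changes of at least 8-fold were found in 141 genes, of which 26 were higher and 115 lower. The groups did not overlap in 13540 genes (88.9%), where chance alone gives 33.3% for 2 libraries against 2. The direction of small changes depended on the scaling between libraries. With library size only, the median gene moved up by 0.34 on the log2 scale, and 8251 genes were higher and 3905 lower (67.9% higher, against 51.6% with TMM scaling). At least 2-fold changes were then 3875 higher and 1159 lower, so a fall of under about 0.34 on the log2 scale becomes a rise with that scaling. RLE factors moved the median gene by -0.047 and gave 5772 higher and 5935 lower (49.3% higher), a test against a 1.5-fold change gave 2652 higher and 2704 lower, and with a pseudocount of 1 RPKM, chosen after seeing the data, 926 genes were at least 2-fold higher and 1304 lower. Whether more genes rose or fell therefore depends on the processing.

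**Figure D1:**
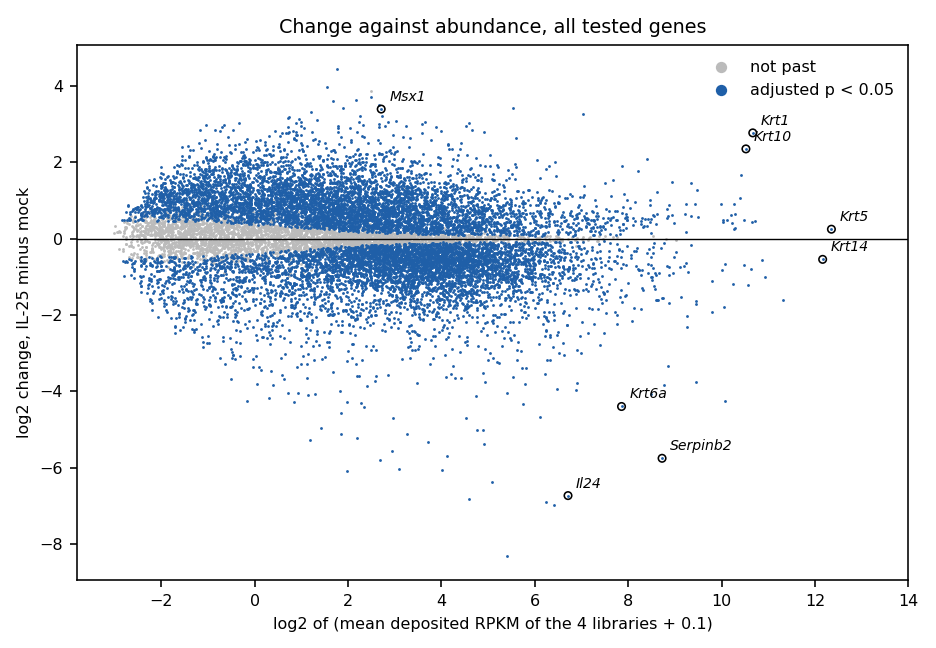
Change of each of the 15229 tested genes against its abundance. The x axis is the log2 of the mean deposited RPKM of the 4 libraries plus 0.1, the y axis the log2 change of TMM-scaled RPKM plus 0.1 (IL-25 minus mock), and each point is a gene, blue where the adjusted p was below 0.05. Il24 (-6.72), Serpinb2 (-5.75) and Krt6a (-4.39) lie far below 0, and Msx1 (3.39), Krt1 (2.76) and Krt10 (2.35) above it.

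Procr, Nppb, Inhba, Il24 and Serpinb2 were among the genes that fell most. Procr, the endothelial protein C receptor (mm10 chromosome 2, 155751117 to 155755471), went from 150.1 ± 0.652 RPKM (SD, n = 2) in mock to 1.51 ± 0.195 with IL-25. Nppb, the brain natriuretic peptide gene (chromosome 4, 147985788 to 147987205), went from 168.1 ± 2.5 to 1.67 ± 0.715 RPKM. Inhba, the activin A subunit (chromosome 13, 16011851 to 16031621), went from 47.3 ± 0.843 to 0.426 ± 0.0633 RPKM, a log2 change of -6.82 ± 0.095 (SE). Il24, an IL-10 family cytokine (chromosome 1, 130882074 to 130887454), went from 206.7 ± 2.5 to 2.39 ± 0.314 RPKM, a log2 change of -6.72 ± 0.083 (limma, Benjamini-Hochberg adjusted p = 2.92e-07). Serpinb2, plasminogen activator inhibitor 2 (chromosome 1, 107511423 to 107535478), went from 825.8 ± 8.62 to 19.5 ± 0.865 RPKM, a log2 change of -5.75 ± 0.035 (adjusted p = 1.44e-07). Adm2, Sprr2g and Sprr2h had log2 changes of -6.02, -5.80 and -5.69. The 5 smallest p values among lower genes were those of Serpinb2, Ifi202b, Epgn, F3 (tissue factor) and Asprv1 (a skin aspartic protease), with log2 changes of -5.75, -4.25, -3.97, -3.84 and -3.76. Gm18445 (-8.29) and Gm12603 (-6.09) also led the list. Gm18445 lies beside Ifi202b on chromosome 1, and the Sprr2 genes are near-identical copies, so how reads were divided among such genes is uncertain. Ifi203, at a low level (0.704 RPKM in mock), lies on the other side of Ifi202b and fell by 2.83. These neighbours span 173920407 to 174001972, and whether their falls are separate responses to IL-25 was not tested.

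Sp5, Msx1 and Foxj1 were among the genes that rose most. Sp5, a zinc finger factor induced by Wnt signals (chromosome 2, 70474923 to 70477729), went from 0.155 ± 0.0729 to 6.42 ± 0.563 RPKM, a log2 change of 4.42 ± 0.227. Msx1, a homeobox factor, and Foxj1, a forkhead factor of ciliated cells, rose by 3.39 and 3.32 on the log2 scale. The enzyme genes Acer1 (an alkaline ceramidase) and Fa2h (a fatty acid hydroxylase) had log2 changes of 3.63 and 3.49. Skint9, Oas1f, Cpsf4l, Gsdmc, Hspa1a and Fam71a changed by 3.95, 3.71, 3.59, 3.42, 3.25 and 3.21. Several of these had low mock levels, such as 0.198 RPKM for Skint9 and 0.248 RPKM for Foxj1, where the added 0.1 RPKM understates the fold.

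All 11 tested genes of the IL-25 receptor and signalling list passed, 4 higher and 7 lower, and 11 also passed when adjusted over the list alone. Il17rb, which binds IL-25, went from 0.285 ± 0.0108 to 1.64 ± 0.127 RPKM, from 19 and 20 reads in mock to 113 and 101 reads with IL-25 (log2 change 1.87 ± 0.143, limma adjusted p = 9.1e-05). Il17rc, a receptor subunit for other IL-17 cytokines, rose by 0.71 on the log2 scale. The shared receptor subunit Il17ra fell by 0.69, the adaptor gene Traf3ip2 (Act1) by 0.56, and the signalling genes Traf3 and Map3k7 by 1.08 and 0.98. As a list these genes did not stand apart from the others (median -0.56, camera adjusted p = 0.409). The median was -0.21 with library size only, where 4 were higher and 6 lower. Il25 itself was not analysed here.

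Cytokine genes moved both ways, with the larger changes downward. Of 24 tested, 7 rose, 14 fell and 3 did not pass, and 21 passed when adjusted over the list alone. Besides Il24, the alarmin gene Il33 went from 31.7 ± 0.95 to 0.500 ± 0.0409 RPKM (log2 change -6.05) and the receptor antagonist Il1rn from 17.4 ± 0.538 to 2.45 ± 0.177 RPKM (log2 change -3.12). Tnf rose from 27.0 ± 0.336 to 80.3 ± 1.46 RPKM (log2 change 1.22). Il1b was near the floor, with 11 and 13 reads in mock and 10 and 5 with IL-25. Its log2 change of -0.74 passed (adjusted p = 0.0401) but not without IL-25 replicate 2 (-0.37, adjusted p = 0.19), without mock replicate 1 (0.0687) or without mock replicate 2 (0.126), nor with library size only (0.136), a replicate block (0.0511), no filter on low reads (0.0646) or, chosen after seeing the data, a pseudocount of 0.01 RPKM (0.0531). The cytokine list had a median of -0.77 and a camera adjusted p of 0.105. These became -1.01 and 0.0318 without IL-25 replicate 1, -1.19 and 0.0268 without IL-25 replicate 2, -1.69 and 0.0259 with a filter of at least 50 reads, and -0.47 and 0.014 with library size only.

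Among 17 chemokine genes, 4 rose, 11 fell and 2 did not pass, with 15 past when adjusted over the list alone. Cxcl14, a chemokine made by resting epithelia, went from 213.7 ± 3.43 to 762.7 ± 7.93 RPKM (log2 change 1.48 ± 0.024). Ccl20, which attracts cells bearing CCR6, went from 7.29 ± 0.0974 to 0.399 ± 0.226 RPKM, and the neutrophil attractants Cxcl1 and Cxcl2 fell by 0.69 and 1.77 on the log2 scale. Cxcl10 and Cxcl16 fell by 1.05 and 1.92. The chemokine list did not stand apart (median -0.77, camera adjusted p = 0.279).

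The 23 NF-kB feedback and target genes were split, 9 higher, 13 lower and 1 not past, with 23 past when adjusted over the list alone. Nfkbia, the gene of the inhibitor IkB-alpha, went from 350.6 ± 5.85 to 1069 ± 0.992 RPKM (log2 change 1.26), and Nfkbiz (IkB-zeta) rose by 1.16. The subunit gene Rela and the kinase gene Ripk2 fell by 1.32 and 1.49. For the list, the median was -0.48 and the camera adjusted p 0.426, and with library size only 9 genes were higher and 10 lower (median -0.18). Of 25 genes of the STAT3 pathway, 8 rose, 15 fell and 2 did not pass, and 24 passed when adjusted over the list alone. Stat3 fell from 48.6 ± 0.884 to 39.0 ± 0.00492 RPKM (log2 change -0.67), with Jak2 and Pim1 at -1.75 and -1.06, while Junb rose by 0.91. This list had a median of -0.50 and a camera adjusted p of 0.307, but with library size only 11 genes were higher and 11 lower (median -0.14). Among 15 antimicrobial and alarmin genes 6 rose and 9 fell, and 15 passed when adjusted over the list alone (median -1.01, camera adjusted p = 0.307). Slpi, a protease inhibitor with antimicrobial activity, went from 52.4 ± 2.59 to 2.02 ± 0.54 RPKM. S100a10 and Defb1 had log2 changes of -1.70 and -1.01, and the RNase gene Rnase4 rose by 1.90. S100a9 fell by 1.94 from 67 and 68 reads to 18 and 24. S100a8 had 7 and 6 reads in mock and 14 in each IL-25 library (log2 change 0.72), a call lost with limma-voom on the reconstructed reads (adjusted p = 0.0968).

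Most keratins of the wound and activation list fell, a list that also holds keratins of simple epithelia and of the companion layer. Of 9 tested, 6 fell, each at least 2-fold, 2 rose and 1 did not pass, with 8 past when adjusted over the list alone. Krt6a (chromosome 15, 101689910 to 101694307) went from 436.5 ± 2.06 to 26.4 ± 2.15 RPKM, a log2 change of -4.39 ± 0.055. Krt16 went from 1318 ± 5.19 to 446.5 ± 3.61 RPKM (-1.91), Krt17 from 3583 ± 1.32 to 1508 ± 1.42 RPKM (-1.60) and Krt75, a companion layer keratin, from 83.9 ± 1.05 to 8.53 ± 0.208 RPKM (-3.63). Krt8 and Krt18, keratins of simple epithelia, fell by 1.59 and 1.93. Krt6b and Krt7 rose by 0.98 and 0.37, Krt7 not without mock replicate 2 (adjusted p = 0.0585), and Krt6a and Krt6b are close copies whose reads may be shared. The list had a median of -1.60 (camera adjusted p = 0.0396, adjusted p = 0.502 with an estimated correlation). Its call was lost without mock replicate 2 (adjusted p = 0.0627).

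Proteases and protease inhibitors of matrix remodelling fell together. Of 21 tested, 16 fell, 12 of them at least 2-fold, 4 rose and 1 did not pass, and 20 passed when adjusted over the list alone. The gelatinase gene Mmp9 went from 58.6 ± 0.833 to 1.69 ± 0.145 RPKM (log2 change -5.38), the metalloprotease gene Adam8 from 100.6 ± 2.05 to 6.32 ± 0.139 RPKM (-4.32), and the urokinase receptor gene Plaur from 74.3 ± 2.43 to 15.0 ± 0.605 RPKM (-2.65). Their median change was -1.36 (camera adjusted p = 9.36e-04, adjusted p = 0.502 with an estimated correlation). In the list of EGFR ligands and growth factors 11 genes rose, 17 fell and 4 of 32 did not pass, with 28 past when adjusted over the list alone. The EGFR ligand genes Epgn and Tgfa went from 216.5 ± 0.271 to 17.5 ± 0.0261 RPKM and from 33.4 ± 0.744 to 3.53 ± 0.075 RPKM. As a list these 32 genes had a median of -0.63 and a camera adjusted p of 0.147, or -0.28 and 0.0308 with library size only, where 14 were higher and 17 lower.

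Basal epidermal genes were lower on balance. All 21 passed, over all genes and when adjusted over the list alone, with 6 higher and 15 lower. Itga2, Itga3 and Itgb1, subunits of integrins that bind collagen and laminin, fell by 3.74, 1.85 and 1.99 on the log2 scale. The main basal keratins changed less. Krt14 went from 4890 ± 54.3 to 4277 ± 4.92 RPKM (log2 change -0.55 ± 0.029) and Krt5 from 4158 ± 150.0 to 6284 ± 151.0 RPKM (0.24 ± 0.04). The Krt5 call was lost after correction for GC content and length, chosen after seeing the data (0.04, adjusted p = 0.412). The list median was -0.55 (camera adjusted p = 0.0174, adjusted p = 0.562 with an estimated correlation), or -0.19 with library size only. All of these genes but Pdpn had a mean of at least 1394 reads. The fifth of tested genes with that many reads had a median change of -0.47, near that of the list, whereas camera compared the list with genes of all abundances.

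Epidermal differentiation genes went both ways. Of 38 tested, 15 rose, 13 of them at least 2-fold, 19 fell, 16 of them at least 2-fold, and 4 did not pass, and 34 passed when adjusted over the list alone. Krt1 (chromosome 15, 101845426 to 101850794) went from 335.8 ± 2.49 to 2913 ± 28.3 RPKM, a log2 change of 2.76 ± 0.024. Its partner Krt10 (chromosome 11, 99385254 to 99389364) went from 392.0 ± 6.77 to 2543 ± 56.2 RPKM, a log2 change of 2.35 ± 0.029. In the other direction, the cross-linking enzyme gene Tgm1 went from 72.9 ± 0.259 to 15.1 ± 0.0625 RPKM (-2.62) and the cornified envelope gene Sprr1b from 170.2 ± 5.89 to 26.3 ± 0.232 RPKM (-3.04). The list median was -0.18 with TMM scaling and 0.16 with library size only, where 19 genes were higher and 17 lower, and the list did not stand apart (camera adjusted p = 0.449).

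Most hair follicle markers of the list rose. Of 16 tested, 13 rose, 9 of them at least 2-fold, 1 fell and 2 did not pass, with 15 past when adjusted over the list alone. The homeobox genes Dlx3 and Lhx2 went from 10.8 ± 0.236 to 85.3 ± 1.85 RPKM (log2 change 2.62) and from 16.9 ± 0.0018 to 79.6 ± 0.82 RPKM (1.88). The hair keratin Krt35 rose by 2.95 and the inner root sheath keratin Krt28 by 2.33. Krt75, a keratin of the follicle's companion layer, was counted with the wound keratins and fell by 3.63. The median was 1.17 (camera adjusted p = 2.15e-04, adjusted p = 0.502 with an estimated correlation). Of 14 Notch pathway genes 9 rose and 5 fell, and 14 passed when adjusted over the list alone. The target genes Hes1 and Nrarp rose by 1.52 and 1.17, while the receptor genes Notch1 and Notch2 fell by 0.81 and 1.16. That list had a median of 0.39 and a camera adjusted p of 0.437.

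**Figure D2:**
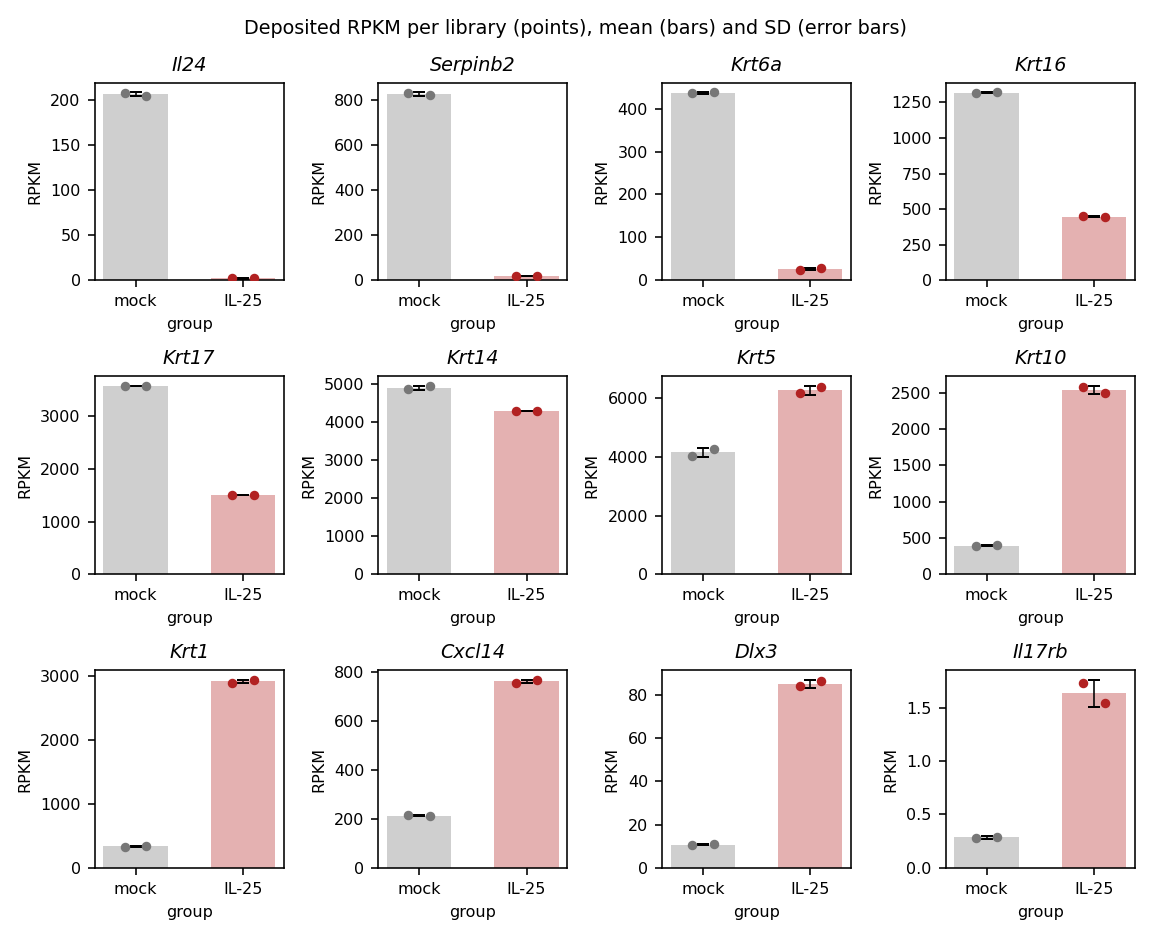
Deposited RPKM (y axis, linear, from 0) of 12 genes in the mock and IL-25 groups (x axis). Points are the 2 libraries of each group, bars their mean and error bars their SD. Il24, Serpinb2, Krt6a, Krt16 and Krt17 were lower with IL-25, Krt1, Krt10, Cxcl14, Dlx3 and Il17rb higher, and Krt14 and Krt5 changed by -0.55 and 0.24 on the log2 scale after TMM scaling.

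Mitotic genes rose almost throughout. Of 31 G2 and M phase genes, 28 rose, 14 of them at least 2-fold, and 3 fell, and 31 passed when adjusted over the list alone. The cyclin gene Ccnb2 went from 5.51 ± 0.218 to 36.1 ± 0.159 RPKM (log2 change 2.34) and Cdca3 from 4.72 ± 0.328 to 26.2 ± 0.31 RPKM (2.10). Foxm1, a transcription factor of mitotic genes, rose by 1.18, Tacc3 by 1.05 and the proliferation marker gene Mki67 by 0.70. The median of these genes was 0.98 (camera adjusted p = 2.02e-05, adjusted p = 0.502 with an estimated correlation). S phase genes moved less. Of 31, 16 rose, 5 fell and 10 did not pass, with 21 past when adjusted over the list alone. Prim1, a primase subunit gene, and Gmnn (geminin) rose by 1.29 and 0.88, while Uhrf1 and the ribonucleotide reductase gene Rrm2 fell by 0.73 and 0.48. That list, with a median of 0.27, was at the threshold (camera adjusted p = 0.04996, adjusted p = 0.513 with an estimated correlation). It was lost with RLE factors (adjusted p = 0.0746), without mock replicate 1 (0.104), without mock replicate 2 (0.0681), and, among settings chosen after seeing the data, with a pseudocount of 1 RPKM (0.0516) and after GC and length correction (0.0623). With library size only 25 genes were higher and 2 lower (median 0.60, adjusted p = 0.0109).

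Genes of the unfolded protein and integrated stress responses fell. Of 36 tested, 32 fell, 13 of them at least 2-fold, 3 rose and 1 did not pass, and 35 passed when adjusted over the list alone. Chac1, a glutathione-degrading enzyme induced by ATF4 (chromosome 2, 119351229 to 119354381), went from 66.2 ± 0.49 to 0.917 ± 0.072 RPKM, a log2 change of -6.36 ± 0.063. The mitochondrial folate enzyme gene Mthfd2 fell by 5.02, asparagine synthetase (Asns) by 3.39 and the transcription factor gene Atf5 by 2.04. The list median was -0.81 (camera adjusted p = 1.47e-07, adjusted p = 0.502 with an estimated correlation). Antioxidant and metallothionein genes were lower too, with 19 of 23 lower, 2 higher and 2 not past, and 21 past when adjusted over the list alone. Heme oxygenase 1 (Hmox1) went from 133.6 ± 6.84 to 14.5 ± 0.662 RPKM (-3.55), Srxn1 fell by 3.78, Txnrd1 by 1.41 and Nfe2l2, the gene of the antioxidant regulator NRF2, by 1.05. This list had a median of -0.88 (camera adjusted p = 1.39e-04, adjusted p = 0.502 with an estimated correlation).

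Of 24 p53 target genes, 16 fell, 5 rose and 3 did not pass, and 21 passed when adjusted over the list alone. Mdm2, the p53 ubiquitin ligase gene, and Pmaip1 (Noxa) fell by 2.01 and 2.12, and Sfn and Phlda3 by 1.21 and 1.13. The median was -0.78 (camera adjusted p = 0.0246, adjusted p = 0.502 with an estimated correlation). Among 30 genes of glycolysis and hypoxia, 19 fell, 8 rose and 3 did not pass, with 27 past when adjusted over the list alone. Ndrg1, a hypoxia-induced gene, went from 203.5 ± 0.485 to 34.2 ± 0.131 RPKM (-2.92), Hif1a fell by 1.57, and the glycolytic enzyme genes Aldoa and Pkm by 1.10 and 1.04. The median was -0.46 (camera adjusted p = 0.0434, adjusted p = 0.502 with an estimated correlation), and the call was lost without IL-25 replicate 1 (adjusted p = 0.0633), without IL-25 replicate 2 (0.0679) and with a filter of at least 50 reads (0.069). With library size only 11 of these genes were higher and 14 lower (median -0.14, adjusted p = 0.0308). Cholesterol and fatty acid synthesis genes went both ways, 19 higher, 12 lower and 3 not past of 34, with 31 past when adjusted over the list alone. Mvk (mevalonate kinase) rose by 2.03 and Msmo1, a sterol methyl oxidase gene, fell by 1.62 (list median 0.28, camera adjusted p = 0.49). The list was 23 higher and 8 lower with library size only (median 0.62).

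Heat shock genes were split with TMM scaling, 7 higher, 8 lower and 3 of 18 not past, but 12 higher and 6 lower with library size only, and 16 passed when adjusted over the list alone. Hspa1a went from 19.7 ± 0.339 to 240.2 ± 3.22 RPKM (log2 change 3.25), Hspa1b rose by 2.07 and the constitutive chaperone gene Hspa8 by 1.37, while Hspa4 fell by 1.33. Hspa1a and Hspa1b are near-identical, so their separate values are uncertain. The median was 0.01, or -0.04 with RLE factors and 0.36 with library size only (camera adjusted p = 0.818). Immediate early and AP-1 genes were higher on balance, with 19 higher, 8 lower and 3 of 30 not past, and 27 past when adjusted over the list alone. Nr4a1, an orphan nuclear receptor gene (chromosome 15, 101254269 to 101274795), went from 80.7 ± 0.0537 to 383.0 ± 0.481 RPKM (1.89), Fos from 288.8 ± 2.01 to 1015 ± 3.73 RPKM (1.46), and Fosb and Jun rose by 1.46 and 1.05. Cyr61, a matricellular gene of the same list, fell by 2.31. Across the list the median was 0.42 (camera adjusted p = 0.0396, adjusted p = 0.502 with an estimated correlation). This call was lost without mock replicate 1 (adjusted p = 0.0604), without mock replicate 2 (0.0656) and after GC and length correction (0.213).

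Interferon-stimulated genes were evenly split with TMM scaling but not with library size only. Of 31 tested, 10 rose, 10 fell and 11 did not pass, against 14 higher and 7 lower with library size only, with 20 past when adjusted over the list alone. Irf1 went from 20.6 ± 0.252 to 110.6 ± 0.769 RPKM (log2 change 2.07), while Gbp2, Ifi203 and Ifitm3 fell by 2.55, 2.83 and 0.99. The median was -0.08, or 0.17 with library size only (camera adjusted p = 0.818). Of 14 antigen presentation genes 4 rose, 6 fell and 4 did not pass, and 10 passed when adjusted over the list alone (median -0.08, camera adjusted p = 0.565). With library size only 7 were higher and 4 lower (median 0.20). H2-K1 and Tapbp fell by 0.92 and 0.69 and Tap1 rose by 0.66, whereas the fall of H2-D1 (-0.38) was not seen with library size only (-0.03, adjusted p = 0.524). Collagen and TGF-beta response genes were 9 higher, 6 lower and 5 not past of 20, with 15 past when adjusted over the list alone. Tgfbi rose by 1.25, and the integrin genes Itgb6 and Itgav fell by 2.82 and 2.53. That list had a median of 0.04 (-0.01 with RLE factors, and 0.39 with library size only, where 13 genes were higher and 4 lower), a mean of -0.13, an upward direction by camera (adjusted p = 0.573) and a downward one by fry.

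Markers of other cell types also differed between the groups. Of 12 fibroblast markers 9 rose and 3 did not pass, and 9 passed when adjusted over the list alone. The tally was 7 higher and 1 lower with RLE factors, and 11 higher and 0 lower with library size only. Dcn (decorin) went from 17.7 ± 0.395 to 65.1 ± 1.51 RPKM and Postn from 40.0 ± 0.127 to 61.5 ± 1.04 RPKM, and the fibroblast median was 0.43 (camera adjusted p = 0.0396, adjusted p = 0.502 with an estimated correlation). Its call was lost without mock replicate 1 (adjusted p = 0.0604) and without mock replicate 2 (0.0656). Leukocyte markers were 12 higher, 2 lower and 4 not past of 18, with 14 past when adjusted over the list alone. Fcer1g, Tyrobp and Coro1a rose by 1.43, 1.02 and 0.85, while Cd74 fell by 0.46, though not with library size only (-0.11, adjusted p = 0.0531). The list median was 0.44 (camera adjusted p = 0.0814). Of 10 melanocyte markers 7 fell, 2 rose and 1 did not pass, with 9 past when adjusted over the list alone. Sox10 and Tyrp1 went from 51.2 ± 2.45 to 11.2 ± 0.00189 RPKM and from 41.1 ± 0.578 to 12.5 ± 1.04 RPKM, and Pmel and Dct fell by 0.78 and 0.47. The median was -0.58 (camera adjusted p = 0.0434, adjusted p = 0.513 with an estimated correlation). The melanocyte call was lost without mock replicate 1 (adjusted p = 0.0604), without IL-25 replicate 1 (0.0633), with a filter of at least 50 reads (0.069) and after GC and length correction (0.054).

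Adipocyte, Schwann cell and red cell markers were 7 lower and 1 not past of 8, with 7 past when adjusted over the list alone. The Schwann cell gene Mbp fell by 1.25, and the globin genes Hba-a1 and Hbb-bs by 0.98 and 1.02, where reads of near-identical globin copies may be shared. The median was -0.89 (camera adjusted p = 0.0287, adjusted p = 0.502 with an estimated correlation). Of 5 endothelial markers 1 rose, 3 fell and 1 did not pass, with 4 past when adjusted over the list alone (median -0.71, camera adjusted p = 0.449), and Flt1 fell by 2.96. The rise, in Egfl7, was lost with RLE factors (limma adjusted p = 0.0618) and with a replicate block (0.0509). The fall of Esam was lost with library size only (0.121) and with no filter on low reads (0.0549). Muscle markers rose in 3 of 4, with 3 past when adjusted over the list alone (median 1.22, camera adjusted p = 0.139). Mylpf and Acta1, at 1.79 RPKM each with IL-25, rose by 1.25 and 1.19. Of 5 mast cell markers 1 rose, 1 fell and 3 did not pass, with 2 past when adjusted over the list alone (median 0.09, camera adjusted p = 0.893). The fall was in Kit (-1.17), which melanocytes express too. Abundant and nuclear RNAs were 7 higher, 4 lower and 1 not past of 12, with 11 past when adjusted over the list alone (median 0.18, camera adjusted p = 0.676). Neat1 and Rn7sk fell by 2.27 and 1.06, and Gas5 rose by 0.66. Mitochondrially encoded RNA held 1.38% and 1.48% of reads in mock and 1.04% and 1.09% in IL-25.

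**Figure D3:**
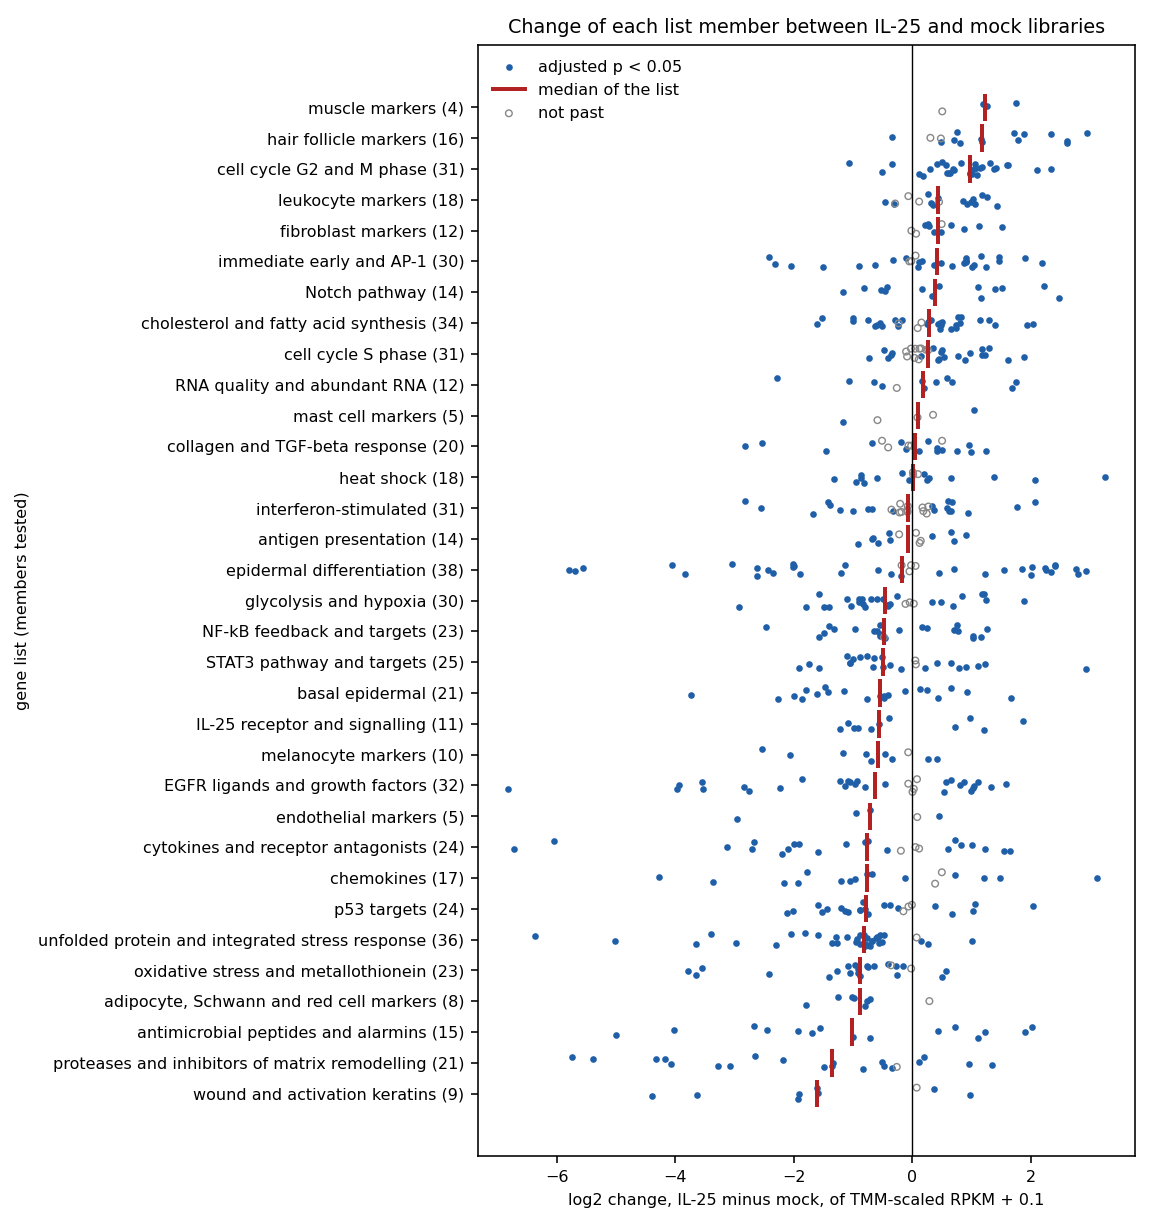
Log2 change (x axis, IL-25 minus mock, of TMM-scaled RPKM plus 0.1) of every tested member of the 33 gene lists (y axis, number of members tested in brackets). Filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians, which run from -1.60 for wound keratins to 1.22 for muscle markers, with hair follicle markers at 1.17.

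Of the 33 lists, 14 were called by camera with a preset correlation, 5 higher and 9 lower, and none of these 14 calls held with an estimated correlation, where camera passed 0 lists (2 at an unadjusted p under 0.05). The power of the estimated form in these data was not measured, so this loss neither shows nor excludes correlated genes. With fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 30 lists passed. The 2 libraries of a group were very close. Over genes with at least 10000 reads in a pair, the coefficient of variation beyond counting noise was 1.74% between the mock libraries and 1.65% between the IL-25 libraries, against 43.1% and 42.8% between groups. The chi-square per gene was 1.51 and 1.41 within groups, above that of sampling alone, so neither pair was counted as 1 library deposited again. Library preparation can add such a spread, which therefore does not show separate cultures.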

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

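The pseudocounts and the GC and length correction were chosen after seeing the data. Counts of genes past the threshold, main 11737, were within 1.5 times under RLE factors, library size only, other filters, limma-voom, other pseudocounts, GC and length correction and with each library left out (10120 to 10955). Against a 1.5-fold change, 5356 genes passed (2652 higher, 2704 lower), a stricter question by construction. Genes at least 2-fold higher and lower, 2392 and 1950, were 3875 and 1159 with library size only, where all genes shift by one factor. With a pseudocount of 1 RPKM, 2230 genes were at least 2-fold changed and 926 higher, since it shrinks low genes, against 4342 and 2392. Of the 14 lists called, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05), and 30 passed with fry; the other alternatives called 11 to 16, and leaving out a library 10 to 14. The log2 change of Tyr, -0.34, was 0.00 with library size only (adjusted p = 0.973), at the size of the shift. Of 192 named genes, 186 kept their side of the threshold after GC and length correction, 188 with RLE factors and 182 with library size only. The replicate numbers are shared between groups, but a pairing is not given, and deviations of same-numbered libraries correlated at -0.043 over all tested genes and at 0.176 over the 3922 genes with the most reads, so a pairing is not excluded; with a replicate block 11650 genes were called. edgeR and DESeq2 alternatives were not run, and limma-voom was the only alternative fitted to the recovered reads. Depth limits low genes: at 10 reads per library a change is known only coarsely, and 2378 genes had reads recovered without a reference length.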

Other observations

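The Hox, hedgehog, Wnt, YAP and SRF, amino acid and one-carbon, ribosomal protein, translation factor and mitochondrial lists, and all tests of explanations below, were chosen after the results were seen. Hox genes were higher in the IL-25 libraries almost throughout: of 27 tested, 26 rose, 24 of them at least 2-fold, and none fell (median 1.76, also 1.76 with 1 gene at 0 mock reads set to its bound, and 1.99 with library size only; camera adjusted p = 3.79e-07, adjusted p = 0.102 with an estimated correlation). Hoxb6 went from 3.07 ± 0.00444 to 24.0 ± 0.189 RPKM and Hoxa5 from 9.31 ± 0.3 to 30.5 ± 0.515 RPKM (SD, n = 2). Hedgehog pathway genes were 10 higher and 1 lower of 12 (median 1.05, adjusted p = 2.79e-04, adjusted p = 0.102 with an estimated correlation), with Gli1, a hedgehog target, going from 16.1 ± 0.591 to 79.0 ± 2.69 RPKM and Ptch1 from 14.6 ± 0.111 to 54.5 ± 1.32 RPKM. Wnt and beta-catenin targets were 13 higher and 2 lower of 16 (median 1.15, adjusted p = 0.00102, adjusted p = 0.102 with an estimated correlation), with Axin2 at a log2 change of 1.91 and Lgr5 at 2.61. Hox levels were low, Hoxa5 having the highest mock level of the 27. Fibroblast markers were 9 higher and 0 lower of 12 in the same libraries, or 7 higher and 1 lower with RLE factors. Leukocyte markers were 12 higher and 2 lower of 18, and muscle markers 3 higher and 0 lower of 4. Which cells carried the Hox, hedgehog and Wnt changes was not tested.

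Targets of YAP and SRF were lower, 16 lower and 2 higher of 19 (median -1.41, adjusted p = 2.97e-06, adjusted p = 0.102 with an estimated correlation), with the TEAD factor genes Tead4 and Tead1 at -4.13 and -1.92 and Axl at -1.81. Amino acid transporters and one-carbon enzymes, which share members with the integrated stress response list, were 17 lower and 1 higher of 18 (median -1.80, adjusted p = 3.46e-07, adjusted p = 0.102 with an estimated correlation). Slc7a3 fell by 5.22 and Slc6a14 by 4.71 on the log2 scale. Ribosomal protein genes were 76 higher and 0 lower of 79 (median 0.54, 0.89 with library size only; adjusted p = 1.68e-14, adjusted p = 0.102 with an estimated correlation) and held 2.13% and 2.07% of mock reads against 3.90% and 3.79% of IL-25 reads. Translation factor genes were 12 higher and 2 lower of 14 (median 0.38, adjusted p = 0.00212, adjusted p = 0.102 with an estimated correlation). Mitochondrially encoded genes were 11 lower and 1 higher of 15 (median -0.69, adjusted p = 8.48e-04, adjusted p = 0.32 with an estimated correlation).

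The number of genes at least 2-fold apart, 4342, could in part reflect technical trends, since the median change rose with GC content from -0.14 in the fifth of genes with the lowest content to 0.19 in that with the highest, and fell with exon length from 0.26 to -0.17. After a spline of GC content was removed from each library, 4268 such genes were counted, and after a spline of length 4272. These trends therefore do not account for the count as a whole. A trend with abundance, from 0.33 in the fifth of genes with the fewest reads to -0.47 in that with the most, was not corrected. The list tests did not compare lists with genes of like abundance, so medians of lists of abundant genes may carry this trend. A response to IL-25 was not tested apart from other differences between the groups.

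Lower wound keratins, proteases and Il24, with higher Krt1, Krt10 and hair follicle genes, may reflect something other than IL-25. Dilution of keratinocytes by another cell type, if it alone gave the fall, would lower Krt5 and Krt14 as much as the wound keratins (median -1.60). Their mean change was -0.15, from -0.55 for Krt14 and 0.24 for Krt5. A partial change in the mix of cells was not tested. Markers of other types also moved apart, with fibroblasts at 0.43 and melanocytes at -0.58. A different culture state of the cells cannot be told apart from a response, because each group is a single condition with no second culture given: the hair follicle median lay 2.77 above that of wound keratins, which both would give. An exchange of the group labels cannot be told apart either, since 70.3% of the 37 chemokine, cytokine and antimicrobial genes at least 2-fold apart were lower in the libraries labelled IL-25, with Tnf higher and Il24 lower, and a response to IL-25 itself remains open.

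Libraries of a group differed little beyond counting noise. A candidate explanation is that both were made from the same culture or RNA pool, for which an excess coefficient of variation under 5% was set as the bound. The higher of the 2 group values was 1.74%, under that bound. The bound was chosen after the results were seen and was not compared with separate cultures. Passing it therefore does not tell a shared pool from separate cultures. Separate cultures handled alike were not tested and remain open, and the adjusted p values hold only for these libraries.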
